A study of Mus musculus with 12 samples.

How the data were processed

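RNA was sequenced in bulk from 12 libraries of mouse thalamus at postnatal day 0, per the series design. Each library came from a pool of 5 brains cut into sections of 300 µm, so the replicates are pools and not single pups. The tissue was microdissected from the ventroposterior medial nucleus, which relays touch from the face to the cortex. The part named PMBSF receives whisker pad input and the part named ALBSF receives upper lip input, per the series design. Control pups (Ctrl) gave 4 libraries of each part, and pups with the treatment that the labels name embWPC gave 4 libraries of ALBSF. The labels do not spell out embWPC, so the name is used as it stands. Messenger RNA was selected with poly-T beads, RNA integrity numbers were above 8, and reads were 150 nucleotides long and paired, per the labels.

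The deposited values are raw counts, which the authors made per Ensembl gene and per library. Per the series design and the submitters' processing notes, reads were checked with FastQC 0.11.9, aligned with STAR 2.7.9a to GRCm39 and handled with SAMtools 1.15. They were then counted with featureCounts of Subread 2.0.1 on Ensembl release 104 genes. The notes also list mm10. Settings for strand, for reads that align to several places and for read pairs are not stated, so counts of overlapping, antisense or nearly identical genes, such as the globin pairs Hba-a1 and Hba-a2 or Hbb-bs and Hbb-bt, are uncertain. The authors' DESeq2 1.32 results were not used here. All values in the files were whole numbers whose totals differed between libraries. The files held 55359 genes, of which 54749 were in GENCODE mouse release 39, which gave symbols and GRCm39 positions. These took 99.98381% of the counts, and the other 610 genes kept their identifier only. The lowest chi-square per degree of freedom between any 2 of the 12 libraries was 14, so no library had been entered more than once. Library totals ran from 28457046 to 34512840 counts. Expression is given as CPM, which are counts scaled to a common library total.

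Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0. The 12 libraries were fitted together with edgeR's quasi-likelihood model and group as the only term. Low counts were filtered with filterByExpr by group, which left 17501 genes, and libraries were scaled by TMM. The common dispersion was 0.0249, a biological coefficient of variation of 15.8%. Ctrl PMBSF was compared with Ctrl ALBSF, embWPC ALBSF with Ctrl ALBSF, and embWPC ALBSF with Ctrl PMBSF. P values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2 scale and come from the edgeR fit. A prior count of 2 was used for log2 CPM values only. Mean CPM values are given with the standard deviation (SD) over the 4 libraries of a group, and log2 fold changes with the standard error (SE) of the fit.

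Gene lists for thalamic cell types, neighbouring tissues, guidance, adhesion, synapses, channels, signalling and cell state were fixed as 36 lists, and 1002 of their 1005 symbols were found in the annotation. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 36 lists of a comparison. It was tested again with an estimated correlation and with fry. Members called were counted after adjustment over all genes and after adjustment over the list alone.

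Genes were named by a fixed rule. For each comparison it took up to 10 called genes with the largest rise and up to 10 with the largest fall. These had a mean of at least 1 CPM over the 8 libraries, groups whose libraries did not overlap, and a symbol that was not a Gm number, a Rik name or a pseudogene. To these it added up to 4 members with the smallest p of each list described, up to 10 genes called in both contrasts against Ctrl ALBSF, and the check genes Xist, Ddx3y, Eif2s3y, Lef1, Slc17a6, Gad2, Dlx6os1, Ttr and Hbb-bs. Dlx6os1 did not pass the count filter. Results of 1 gene that this rule takes, and of a list described by it, are not reported here. The lists, this rule, the tests and most alternatives were chosen before the data were examined, and those chosen later are named in the closing parts.

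Both contrasts against Ctrl ALBSF use the same 4 control libraries, which gives them shared noise. The shift of embWPC ALBSF towards Ctrl PMBSF was therefore measured with split controls. In each of the 6 ways to split the Ctrl ALBSF libraries, 2 of them were set against Ctrl PMBSF to pick the genes that differ. The remaining 2 were set against embWPC ALBSF to measure those genes. Genes were picked with limma-trend on log2 CPM at an adjusted p under 0.05, or as the 200 with the smallest p where fewer than 20 passed. The statistic was the median log2 difference signed by the direction of the control contrast, averaged over the 6 splits. Its two-sided exact permutation test, which takes no account of the numbers of the libraries, ran over the 70 ways to assign the 8 ALBSF libraries to control and embWPC. In an added alternative, genes were picked with 2 Ctrl PMBSF libraries whose numbers are not those of the held-out Ctrl ALBSF libraries, averaged over the possible choices of 2. The real assignment leaves 1 such choice per split, and assignments that hold out embWPC libraries leave more. The permutation p of this alternative is therefore not exact. A position between the control groups was also computed for every library from CPM of the genes called between them, with each control library left out of its own reference. Positions of control libraries with the genes called again without the scored library were added after the values were seen. The share of PMBSF expression in embWPC ALBSF was fitted on the same called genes in another way. The difference between the control groups was taken from 2 libraries of each, and embWPC ALBSF was measured against the remaining 2 of each. The share was averaged over all such choices, as 1 number for all called genes and for higher and lower genes apart.

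The code was tested on simulated data with the dispersions and totals of these libraries. For Ctrl PMBSF against Ctrl ALBSF, 50 genes each were given a change of 1.5, 2, 3 or 4-fold among 17501. The edgeR fit recovered 62% of them at 1.5-fold, 90% at 2-fold, 100% at 3-fold and 100% at 4-fold, none in the wrong direction, and 11 of its 187 calls were false. DESeq2 recovered 76%, 94%, 100% and 100%, with 35 false calls among 220. A simulated share of 0.5 was recovered as 0.504 from the genes given a change of at least 2-fold. The calling of genes was not part of that check. In 20 simulations with neither an embWPC effect nor a territory difference, the mean shift was -0.00168.

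Sample titles carry a number from 1 to 4, and nothing in the labels says that a number marks a shared pool or litter. The counts were used to check this. Deviations from the group mean correlated across genes between Ctrl ALBSF and Ctrl PMBSF libraries of the same number at 0.386, 0.225, 0.315 and 0.395, and the highest value between different numbers was 0.0779. The numbers therefore pair the control libraries, and a fit of the 8 control libraries with the number as a block was added. Alternatives were DESeq2 with its own size factors, its size factors or upper-quartile scaling in edgeR, no count filter or a stricter one of at least 1 CPM in 4 libraries, only the 8 libraries compared, the number as a block, voom with quality weights, 1 surrogate variable, contaminant genes left out, a fold minimum of 1.5, and each library left out in turn.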

Results

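Poly-A RNA was counted in 4 libraries each of Ctrl ALBSF, Ctrl PMBSF and embWPC ALBSF. Library totals ran from 28457046 to 31850727 counts in Ctrl ALBSF, from 31921767 to 34512840 in Ctrl PMBSF and from 31712820 to 33702453 in embWPC ALBSF. Genes of the mitochondrial genome took 1.72 to 3.45% of the counts of a library. The most abundant gene in each library was Tuba1a, an alpha-tubulin of young neurons, with 2.98 to 4.37% of its counts. Slc17a6, the vesicular glutamate transporter of thalamic relay neurons, had a log2 difference of 0.04 ± 0.08 (SE, n = 4 per group) between Ctrl PMBSF and Ctrl ALBSF with an adjusted p of 0.919. Lef1, a transcription factor of thalamic neurons, had a difference of -0.08 ± 0.09 with an adjusted p of 0.788.

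Comparing Ctrl PMBSF with Ctrl ALBSF asks how the whisker pad and upper lip territories of the ventroposterior medial nucleus differ at birth. Among genes higher in PMBSF, Tll1, a tolloid-like metalloprotease, rose 5.58-fold, from 2.35 ± 0.89 to 13.1 ± 2.9 CPM (mean ± SD, n = 4; log2 change 2.48 ± 0.25 (SE), adjusted p = 0.000293). Dlk1, a membrane protein related to Notch ligands, rose 5.18-fold (log2 2.37 ± 0.31, adjusted p = 0.00153), and Wif1, a secreted Wnt inhibitor, rose 4.64-fold (adjusted p = 0.00391). Hs6st2, a heparan sulfate sulfotransferase, rose 3.42-fold, from a mean of 12.9 to 44.2 CPM (adjusted p = 0.000365). Tmem182 and Tpd52l1 rose 3.90-fold and 3.06-fold. Hdc, which makes histamine, rose 3.14-fold (adjusted p = 0.00504).

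On the ALBSF side, the keratin gene Krt19 fell by 3.76 ± 0.66 on the log2 scale in PMBSF (SE, n = 4 per group), from a mean of 11 to 0.802 CPM, with an adjusted p of 0.00821. Inhba, a subunit of activin, fell by 2.64 ± 0.39 (adjusted p = 0.00318), and Cpne6, a calcium-binding copine, fell by 2.47 ± 0.37 (adjusted p = 0.00336). Cntn3, a contactin cell adhesion protein, fell by 2.36 ± 0.32 (adjusted p = 0.00176). Cdh9, a type II cadherin, fell by 2.29 ± 0.33, from 3.21 ± 1.3 to 0.650 ± 0.16 CPM (adjusted p = 0.00275). Ano3, the Wnt signal enhancer Rspo3 and the lipase gene Pnlip fell by 2.07, 1.99 and 1.92. In all, 142 genes were higher and 142 lower in PMBSF among 17501 tested with edgeR, and 2068 had an unadjusted p under 0.05. Of the 284 called genes, 265 were protein coding and 14 were long noncoding RNAs. The 4 libraries of one group all lay above the other 4 for 281 of the 284, and for 8.28% of all genes tested, where chance gives 2.86%.

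Lists of cell adhesion and synapse genes were lower in PMBSF. Of 42 synaptic organiser genes, 4 rose and 6 fell, and 5 rose and 10 fell when adjusted over the list alone. Adgrl2, a latrophilin that binds teneurins across the synapse, fell by 1.39 ± 0.07 (SE, n = 4 per group), from 171 ± 8.3 to 65.2 ± 1.7 CPM, with an adjusted p of 6.10e-08. The teneurins themselves parted, with Tenm1 down by a log2 change of -1.03 ± 0.10 (adjusted p = 0.000293) and Tenm3 up by 0.77 ± 0.11 (adjusted p = 0.00191). Slitrk6 fell by 1.06 ± 0.15 (adjusted p = 0.00269). As a set the organisers were lower at an adjusted p of 1.61e-06 by camera, and at an adjusted p = 0.192 with an estimated correlation. Of 17 classical and type II cadherins, 1 rose and 6 fell, with 2 and 6 adjusted over the list alone. Besides Cdh9, Cdh10 fell by 0.96 ± 0.13, Cdh4 by 0.76 ± 0.12 and Cdh6 by 0.67 ± 0.10. The cadherins were lower at an adjusted p of 0.000219, or adjusted p = 0.112 with an estimated correlation. Of 11 delta protocadherins, 2 fell, Pcdh11x by 1.24 ± 0.13 and Pcdh10 by 0.94 ± 0.12, and 4 fell when adjusted over the list alone. That list was lower at an adjusted p of 1.57e-05, or adjusted p = 0.112 with an estimated correlation.

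Genes that define thalamic neurons differed in both directions. Of 30 thalamic relay neuron genes, 4 rose and 8 fell, with 6 and 10 adjusted over the list alone. The nuclear receptors Rorb and Nr2f2 fell by 1.17 ± 0.12 and 1.13 ± 0.16 (SE, n = 4 per group). The transcription factor gene Pou2f2 rose 2.06-fold (adjusted p = 0.00101), and Htr1b, a serotonin receptor of thalamic axons, rose by 0.84 ± 0.12 (adjusted p = 0.00231). The relay list was lower at an adjusted p of 0.00324, or adjusted p = 0.112 with an estimated correlation. Of 21 genes that separate first-order from higher-order thalamic nuclei, 3 rose and 1 fell, with 3 and 3 adjusted over the list alone. Tnnt1, a marker of first-order nuclei, rose 2.67-fold (log2 change 1.42 ± 0.18, adjusted p = 0.00147). That list was not called, at an adjusted p of 0.859, and its median of -0.13 had another sign than its mean of 0.02 and its test.

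Axon guidance lists were lower in PMBSF. Of 30 semaphorins, plexins and neuropilins, only Plxna2, a semaphorin receptor, was called and fell by 1.53 ± 0.16 (SE, n = 4 per group, adjusted p = 0.000293), while 5 fell when adjusted over the list alone. The list was lower at an adjusted p of 9.08e-06, or adjusted p = 0.215 with an estimated correlation. Of 33 netrin, Slit and other guidance genes, 2 fell, Cntn3 and the Slit receptor Robo1 (by 0.84 ± 0.13), and 2 rose and 2 fell when adjusted over the list alone. That list was lower at an adjusted p of 0.00324, or adjusted p = 0.411 with an estimated correlation. Of 22 ephrins and Eph receptors, 1 rose and 2 fell, and 1 and 3 adjusted over the list alone. Epha4 fell by 0.45 ± 0.09 (adjusted p = 0.0199), a call lost without Ctrl ALBSF 2, 3 or 4 or Ctrl PMBSF 1 or 2, at adjusted p values of 0.0502 to 0.0594. The list was lower at an adjusted p of 0.0192, or adjusted p = 0.366 with an estimated correlation. It was not called without Ctrl ALBSF 1 (adjusted p = 0.0566) or without Ctrl PMBSF 2 (adjusted p = 0.103).

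Of 49 Wnt, Bmp, Shh, Notch and retinoic acid signalling genes, 3 rose and 1 fell, with 5 and 3 adjusted over the list alone. Sfrp2, a secreted Wnt-binding protein, rose by 0.61 ± 0.11 (SE, n = 4 per group, adjusted p = 0.00893). Of 46 extracellular matrix and proteoglycan genes, 2 rose and 1 fell, with 5 and 6 adjusted over the list alone. These included Hs6st2 and the glypican gene Gpc5, which rose by 1.40 ± 0.18 (adjusted p = 0.00153). Neither list was called as a set, at adjusted p values of 0.766 and 0.675. Their medians of -0.07 and -0.15 and their tests pointed down, and their means of 0.02 and 0.05 pointed up.

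Glutamate receptor, potassium channel and presynaptic lists were lower in PMBSF as sets. Of 24 glutamate receptor genes, 2 fell, among them Grm4 by 0.77 ± 0.14 (SE, n = 4 per group, adjusted p = 0.0113), and 1 rose and 8 fell when adjusted over the list alone. The list was lower at an adjusted p of 9.08e-06, or adjusted p = 0.193 with an estimated correlation. Of 46 potassium channel genes, 1 rose and 2 fell, and 2 and 3 adjusted over the list alone. Kcnip4 rose by 0.75 ± 0.13, and Kcnd2 and Kcnab1 fell by 0.56 ± 0.09 and 1.09 ± 0.20. This list was lower at an adjusted p of 0.00102, or adjusted p = 0.383 with an estimated correlation. Of 42 presynaptic and neuronal maturation genes, 2 fell, among them Cplx2, a complexin of vesicle release, by 1.01 ± 0.17 (adjusted p = 0.00647), and 1 rose and 3 fell when adjusted over the list alone. It was lower at an adjusted p of 0.000150, or adjusted p = 0.252 with an estimated correlation.

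Of 38 monoamine and neuropeptide signalling genes, 2 rose, Htr1b among them, and 1 fell, the neuropeptide Y receptor Npy1r by 0.85 ± 0.15 (SE, n = 4 per group), with 4 and 2 adjusted over the list alone. The set was not called, at an adjusted p of 0.639, and had a median of -0.05 against a mean of 0.02 and an upward test. Of 16 oligodendrocyte lineage markers, 1 rose and 1 fell, with 1 and 5 adjusted over the list alone, and the list was not called at an adjusted p of 0.0518.

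Markers of tissue around the nucleus were measured beside these genes. Of 17 meningeal fibroblast markers, 16 had a higher value in Ctrl PMBSF, with a median of 0.88. The edgeR fit called 0 of them over all genes, 8 had an unadjusted p under 0.05, 8 passed adjusted over the list alone, and DESeq2 and voom called 1 each. Col3a1, a collagen of connective tissue, had a log2 difference of 1.67 ± 0.46 (SE, n = 4 per group) and an adjusted p of 0.101. The meningeal list was higher at an adjusted p of 1.57e-05, or adjusted p = 0.252 with an estimated correlation. The mean log2 CPM of the list was 2.61 in Ctrl PMBSF 2, 1.68 and 1.76 in Ctrl PMBSF 3 and 4, and 0.920 in Ctrl PMBSF 1, which lay within the 0.704 to 1.1502 of Ctrl ALBSF. Col3a1 was called in 3 of 24 alternatives, which were no count filter (adjusted p = 0.00143), Ctrl PMBSF 1 left out and both control libraries numbered 1 left out, with a difference of up to 2.06. Dcn and Col1a2 were also called in 3 and Islr in 4 of 24. Without Ctrl PMBSF 2 the difference of Col3a1 was 0.84 (adjusted p = 0.247), and the list stayed under 0.05 by camera with the preset correlation. Of 19 prethalamic and reticular GABAergic neuron markers, edgeR, DESeq2 and voom called 0, 1 had an unadjusted p under 0.05, and 0 passed adjusted over the list alone. That list had an adjusted p of 0.835, with a median of -0.12 against a mean of 0.10 and an upward test. Gad2, which makes GABA, had a difference of 0.21 and an adjusted p of 0.937.

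Vessel, blood and mitochondrial lists were lower in PMBSF. Of 23 endothelial and mural cell markers, 5 had a higher value, and edgeR, DESeq2 and voom called 0, with 5 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Endothelial genes were lower as a set at an adjusted p of 0.00182, or adjusted p = 0.580 with an estimated correlation, and was not called without Ctrl ALBSF 1 (adjusted p = 0.0534) or Ctrl PMBSF 4 (adjusted p = 0.0532). Of 8 erythroid genes, 1 had a higher value and 1 fell, also adjusted over the list alone. As a set they were lower at an adjusted p of 0.0188, or adjusted p = 0.411 with an estimated correlation, and was not called without Ctrl PMBSF 1 (adjusted p = 0.0518). All 12 mitochondrially encoded genes tested had lower values, with a median of -0.29. The edgeR fit, DESeq2 and voom called 0 of them and 0 had an unadjusted p under 0.05. Their list was lower at an adjusted p of 0.00858, or adjusted p = 0.657 with an estimated correlation, and was not called without Ctrl ALBSF 2 (adjusted p = 0.111) or Ctrl PMBSF 1 (adjusted p = 0.147).

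The count of 284 depended on the fit and on single libraries. DESeq2 called 527 genes, voom with quality weights 443, and a fit with the mean meningeal level of each library as covariate 182, of which 108 were among the 284. Under that covariate Krt19, Inhba, Cdh22, Slitrk6, Epha4, Robo1, Grm4, Kcnab1, Npy1r and Sfrp2 missed the threshold, at adjusted p values of 0.0525 to 0.213. Their log2 changes kept their sign, at -3.58, -2.23, -0.696, -0.954, -0.33, -0.768, -0.537, -1.07, -0.844 and 0.629 in that order. Without both control libraries numbered 1, Kcnip4 (0.0511) and Epha4 (0.102) missed it. With the replicate number as a block in the 8 control libraries, which the numbers pair, 857 genes were called (413 higher, 444 lower), and 283 of the 284 were among them. The count was 160 without Ctrl ALBSF 2, 127 without Ctrl ALBSF 3, 155 without Ctrl ALBSF 4 and 163 without Ctrl PMBSF 2.

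Comparing embWPC ALBSF with Ctrl ALBSF asks what the treatment changed in the upper lip territory. Of 11 genes called, 3 rose and 8 fell. Adgrl2 (ENSMUSG00000028184, GRCm39 chromosome 3, 148518957 to 148696229) fell by 0.60 ± 0.07 on the log2 scale (SE, n = 4 per group), from 171 ± 8.3 to 113 ± 7.1 CPM (SD), with an adjusted p of 0.00425. Cdh9 (ENSMUSG00000025370, chromosome 15, 16728507 to 16857226) fell by 2.44 ± 0.34, from a mean of 3.21 to 0.589 CPM (adjusted p = 0.0215). Penk, the precursor of enkephalins (ENSMUSG00000045573, chromosome 4, 4132722 to 4141856), fell by 2.62 ± 0.37, from 3.23 ± 1.4 to 0.519 ± 0.095 CPM (adjusted p = 0.0215). Tll1 (ENSMUSG00000053626, chromosome 8, 64466142 to 64659305) rose 3.47-fold, from 2.35 ± 0.89 to 8.14 ± 1.5 CPM (adjusted p = 0.0215).

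The other called genes in embWPC ALBSF had adjusted p values of 0.0441 to 0.0486. Pou2f2 (chromosome 7, 24786769 to 24879151) rose 1.67-fold, from a mean of 35.4 to 59.1 CPM (n = 4 per group), and Dcdc2a, a doublecortin domain gene (chromosome 13, 25239454 to 25394689), rose 1.48-fold. The neurexin ligand Nxph1 (chromosome 6, 8948431 to 9249616) fell by 1.21 ± 0.19 (SE), and the type II cadherin Cdh22 (chromosome 2, 164953045 to 165076940) by 0.98 ± 0.15. Plxna2 (chromosome 1, 194300526 to 194499177) fell by 0.95 ± 0.15, and Lmo4, a LIM-only transcription regulator (chromosome 3, 143894143 to 143911774), by 0.92 ± 0.15. Pcdh10 (chromosome 3, 45332833 to 45390058) fell by 0.77 ± 0.12. Of the 11 genes, 10 also differed between Ctrl PMBSF and Ctrl ALBSF in the same direction, 3 upwards and 7 downwards. Penk was not called there, with 1.45 CPM in Ctrl PMBSF, a log2 difference of -1.15 ± 0.33 from Ctrl ALBSF, an unadjusted p of 0.00396 and an adjusted p of 0.133. Between embWPC ALBSF and Ctrl PMBSF it had a difference of -1.47 and an adjusted p of 0.298. No gene was called in opposite directions. Both contrasts share the Ctrl ALBSF libraries, so this overlap is not that of independent lists.

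**Figure D1:**
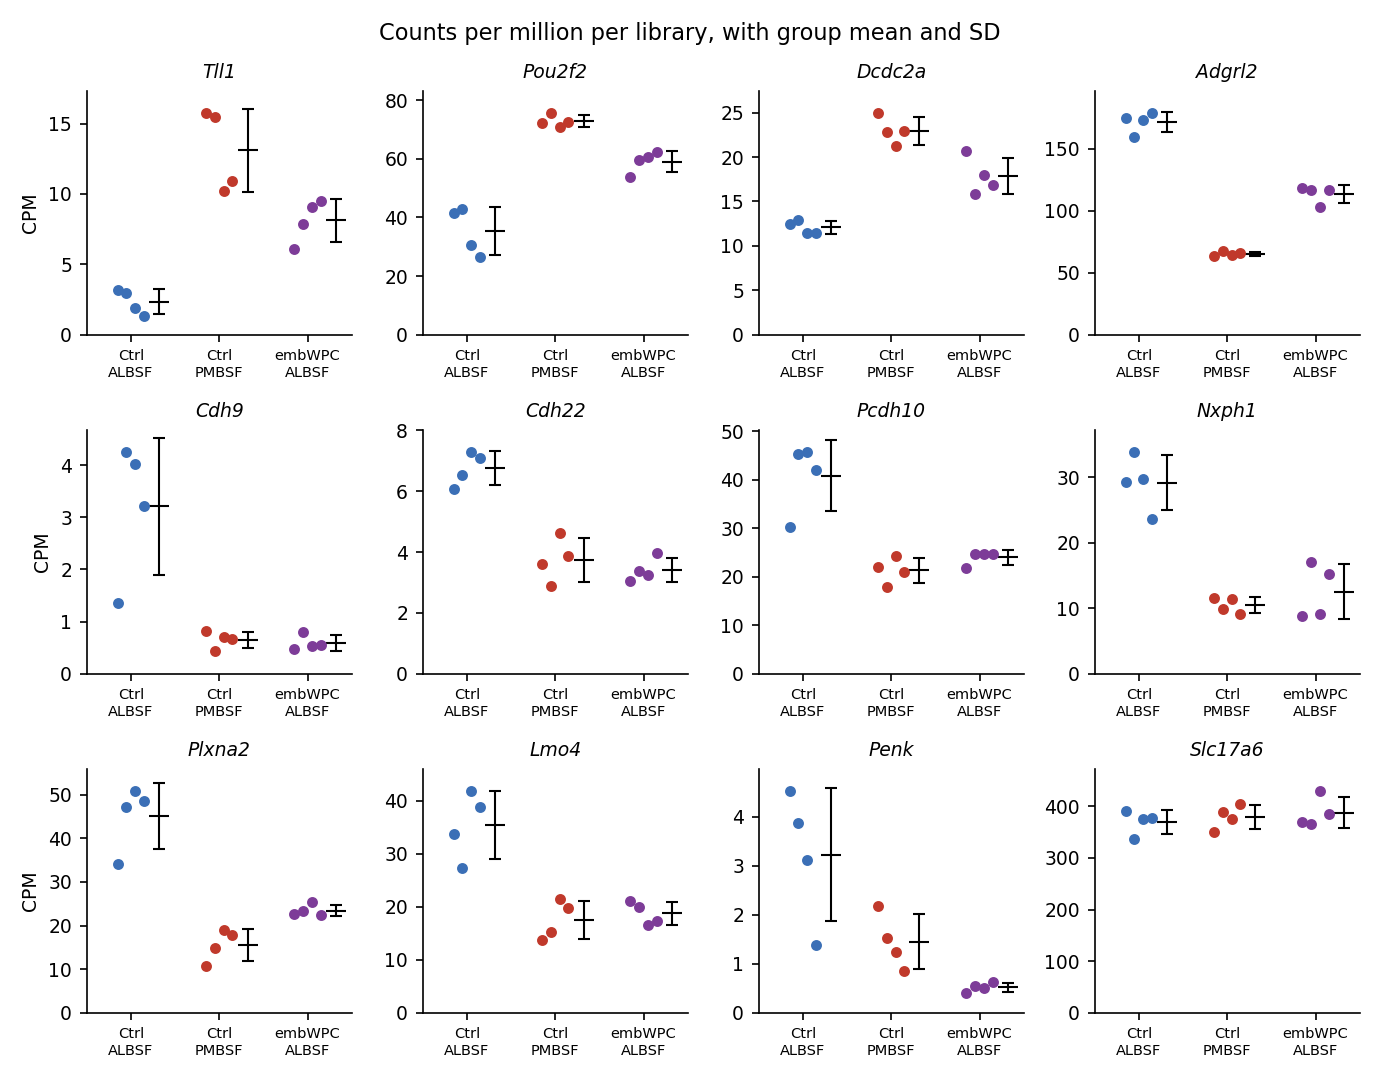
Expression in CPM (vertical axes, from 0) of 12 genes in each of the 12 libraries, with Ctrl ALBSF, Ctrl PMBSF and embWPC ALBSF along the horizontal axes, points as libraries and bars as group mean and SD (n = 4). In the Adgrl2 panel the embWPC ALBSF mean of 113 CPM lies between 171 in Ctrl ALBSF and 65.2 in Ctrl PMBSF, and in the Penk panel it lies at 0.519 against 3.23 CPM in Ctrl ALBSF.

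Several lists that were lower in Ctrl PMBSF were also lower in embWPC ALBSF. Both contrasts use the same Ctrl ALBSF libraries, whose noise can by itself make a list lower in both. The lists were not tested with split controls. Of 17 cadherins, 2 fell, and 2 rose and 5 fell when adjusted over the list alone. Of 11 delta protocadherins, 1 fell, and 3 adjusted over the list alone. Of 42 synaptic organisers, 1 fell, and 2 rose and 5 fell adjusted over the list alone. The 3 lists were lower at adjusted p values of 0.00256, 0.00568 and 0.00497, or adjusted p = 0.348 with an estimated correlation for each. Members that were not called included Cdh10 with a log2 difference of -0.68 (adjusted p = 0.0707), Pcdh11x with -0.65 (adjusted p = 0.0707) and Tenm1 with -0.56 (adjusted p = 0.0648). Of 30 semaphorins, plexins and neuropilins, 1 fell, with 1 rising and 1 falling adjusted over the list alone, and the list was lower at an adjusted p of 0.0156, or adjusted p = 0.440 with an estimated correlation. Of 33 netrin, Slit and other guidance genes, edgeR called 0 over all genes, 13 had an unadjusted p under 0.05, 5 fell adjusted over the list alone, and DESeq2 and voom called 2 each. Robo1 had a difference of -0.58 (adjusted p = 0.107). The guidance list was lower at an adjusted p of 0.000682, or adjusted p = 0.348 with an estimated correlation.

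Without embWPC ALBSF 1, the cadherin, delta protocadherin, synaptic organiser and semaphorin lists were not called in this contrast, at adjusted p values of 0.0699, 0.0911, 0.161 and 0.166. The semaphorin list was also not called without Ctrl ALBSF 1 (adjusted p = 0.0549) or Ctrl ALBSF 2 (adjusted p = 0.0612).

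Thalamic identity lists were not called in embWPC ALBSF. Of 30 thalamic relay neuron genes, Pou2f2 rose, and 4 rose and 6 fell when adjusted over the list alone, with a set adjusted p of 0.148. Of 21 genes separating first-order and higher-order nuclei, Penk fell, and 2 rose and 3 fell adjusted over the list alone, with a set adjusted p of 0.0831. Tnnt1 had a log2 difference of 0.73 (adjusted p = 0.15) and was not called. Of 46 extracellular matrix and proteoglycan genes, edgeR called 0 over all genes, 9 had an unadjusted p under 0.05, 4 rose and 1 fell adjusted over the list alone, and DESeq2 and voom called 3 each. Hs6st2 had a difference of 1.09 (adjusted p = 0.0598) and Gpc5 of 0.85 (adjusted p = 0.103). That set had an adjusted p of 0.497, with a median of -0.05 and a mean of -0.00 against an upward test.

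Erythroid, meningeal and astrocyte lists were lower in embWPC ALBSF by camera with the preset correlation, while fry called 0 lists in this contrast. Camera also called the choroid plexus, hypothalamic, telencephalic, proliferation and sex-linked lists. In that order, 3 of 11, 0 of 9, 1 of 16, 2 of 27 and 0 of 5 members tested had an unadjusted p under 0.05. All 8 erythroid genes tested were lower, with a median of -0.71, and 4 fell adjusted over the list alone. The edgeR fit called 0 of them over all genes, 5 had an unadjusted p under 0.05, and DESeq2 and voom called 1 and 0. Hbb-bs, an adult beta globin, had 246 ± 73 CPM (SD, n = 4) against 412 ± 67 CPM in Ctrl ALBSF (adjusted p = 0.168). The erythroid list was lower at an adjusted p of 1.54e-06, or adjusted p = 0.348 with an estimated correlation. Of 17 meningeal markers, 2 had a higher value, edgeR called 0 over all genes, 2 had an unadjusted p under 0.05, 1 fell adjusted over the list alone, and DESeq2 and voom called 1 and 0. The meningeal list was lower at an adjusted p of 0.00256, or adjusted p = 0.348 with an estimated correlation. Of 26 astrocyte and radial glia markers, 7 had a higher value, edgeR called 0 over all genes, 5 had an unadjusted p under 0.05, 1 fell adjusted over the list alone, and DESeq2 and voom called 1 and 0. The astrocyte list was lower at an adjusted p of 0.0125, or adjusted p = 0.397 with an estimated correlation. The astrocyte list was not called without Ctrl ALBSF 1 (adjusted p = 0.289) or without embWPC ALBSF 2 (adjusted p = 0.152). Of 16 oligodendrocyte lineage markers, 8 had a higher value, and that list was not called at an adjusted p of 0.975.

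Prethalamic and reticular GABAergic neuron markers were lower in embWPC ALBSF than in both control groups. Of the 19 tested, 3 had a higher value than in Ctrl ALBSF, with a median of -0.52, and edgeR, DESeq2 and voom called 0, with 2 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Together they were lower at an adjusted p of 0.0154, or adjusted p = 0.582 with an estimated correlation, and was not called without Ctrl ALBSF 1 (adjusted p = 0.713) or embWPC ALBSF 1 (adjusted p = 0.0911). Against Ctrl PMBSF, 2 of the 19 had a higher value, with a median of -0.63, and edgeR, DESeq2 and voom called 0, with 2 at an unadjusted p under 0.05 and 0 adjusted over the list alone. There the list was lower at an adjusted p of 0.00806, or adjusted p = 0.659 with an estimated correlation, and was not called without Ctrl PMBSF 2 (adjusted p = 0.0525) or Ctrl PMBSF 3 (adjusted p = 0.0662).

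The count of 11 rested on the tool and on single libraries, while 1614 genes had an unadjusted p under 0.05 and the fold of the 11 kept its sign in every fit. DESeq2 called 181 genes, voom 75, and edgeR without a count filter 121, each with all 11 among them, while the stricter filter left 5 and the other 6 had adjusted p values of 0.0514 to 0.0527. A fit with 1 surrogate variable called 34, the replicate number as a block called 23, the meningeal level as covariate called 35, and leaving out both control libraries numbered 1 called 50. Without Ctrl ALBSF 3 or without embWPC ALBSF 3 the count was 1, which was Adgrl2, and the other 10 genes had adjusted p values of 0.119 to 0.212 and 0.144 to 0.154. It was 22 without Ctrl ALBSF 1, 4 without Ctrl ALBSF 2, 3 without Ctrl ALBSF 4, 37 without Ctrl PMBSF 1, 4 without Ctrl PMBSF 4 and 2 without embWPC ALBSF 1. Genes that missed the threshold had adjusted p values of 0.0566 without Ctrl ALBSF 1, 0.0636 to 0.123 without Ctrl ALBSF 2, 0.0557 to 0.139 without Ctrl ALBSF 4, and 0.127 without embWPC ALBSF 1. These values were 0.0544 without Ctrl PMBSF 2, 0.0509 to 0.0648 without Ctrl PMBSF 3, 0.0662 to 0.0860 without Ctrl PMBSF 4, 0.0871 to 0.0960 without embWPC ALBSF 2 and 0.0668 to 0.0769 without embWPC ALBSF 4.

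Across the genes that part the control territories, embWPC ALBSF lay between them. On a scale where the Ctrl ALBSF mean is 0 and the Ctrl PMBSF mean is 1, the 4 embWPC ALBSF libraries sat at 0.577 ± 0.077 (SD, n = 4), from 0.506 to 0.661. The genes were called with these control libraries, which by itself parts the control positions. With the genes called again without the scored library and that library left out of the reference, Ctrl ALBSF libraries sat at 0.069 ± 0.18, from -0.0999 to 0.307, and Ctrl PMBSF libraries at 0.864 ± 0.086, from 0.806 to 0.991. On the genes and references used for each left-out Ctrl ALBSF library, 127 to 249 genes, the embWPC ALBSF libraries sat between 0.507 and 0.694. On those used for each left-out Ctrl PMBSF library, 163 to 213 genes, they sat between 0.472 and 0.671. Of the 142 genes higher in Ctrl PMBSF, 140 were higher in embWPC ALBSF than in Ctrl ALBSF, and of the 142 lower genes 139 were lower. Among all genes the 2 contrasts had the same sign in 66.9%. These counts use the same Ctrl ALBSF libraries on both sides and are raised by that.

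**Figure D2:**
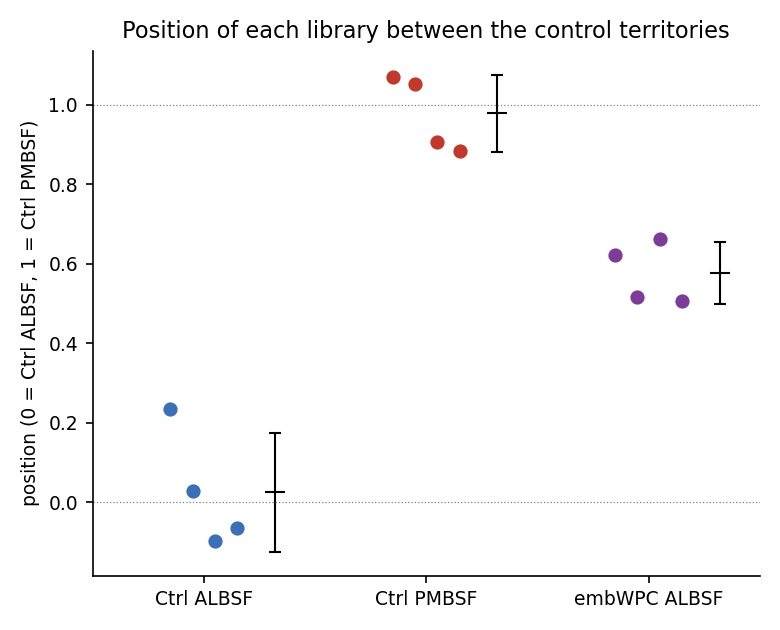
Position of each library (points) between the means of Ctrl ALBSF, set to 0, and Ctrl PMBSF, set to 1, over the 284 genes called between them, with the group mean and SD as bars (n = 4). Control libraries took part in the choice of these genes and are left out only of their own reference. The embWPC ALBSF libraries lie from 0.506 to 0.661, above all Ctrl ALBSF libraries (-0.098 to 0.236) and below all Ctrl PMBSF libraries (0.882 to 1.07).

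With split controls, which remove the noise of libraries used on both sides, territory genes were shifted by a median log2 difference of 0.508 towards Ctrl PMBSF in embWPC ALBSF, between 0.424 and 0.624 in the 6 splits. The two-sided exact permutation p was 0.0143, the smallest that the 70 assignments allow, and the largest shift among the others was 0.286 in size. Simulations with neither an embWPC effect nor a territory difference averaged -0.00168. They do not show what an unchanged embWPC group would give beside a real territory difference. Same-numbered Ctrl ALBSF and Ctrl PMBSF libraries deviated together, which neither the permutation nor the simulations account for. With territory genes picked from 2 Ctrl PMBSF libraries that share no number with the held-out Ctrl ALBSF libraries, the shift was 0.498, between 0.387 and 0.635 in the 6 splits. Its permutation p was 0.0143, which is not exact because other assignments average over more choices of libraries. Without Ctrl ALBSF 1, 2, 3 and 4 in turn the shift was 0.659, 0.363, 0.309 and 0.321, each with an exact permutation p of 0.0286. In these fits only 1 Ctrl ALBSF library picked the genes and the other 2 measured them, so their size is not directly comparable with 0.508. Without splitting, the shift was 0.442 over 238 selected genes, with an exact permutation p of 0.0143. With the replicate number as a block and no splitting it was 0.207 over 1410 selected genes. Its permutation p of 0.0143 is not exact, because the block was removed before the libraries were reassigned without regard to number. The choice of genes did not count the degrees of freedom of the block, which by itself raises their number. Leaving out Ctrl ALBSF 1 without splitting gave 0.518 with an exact permutation p of 0.0571. Leaving out Ctrl ALBSF 2, 3 and 4 in turn without splitting gave 0.539, 0.570 and 0.543, each with an exact permutation p of 0.0286. Across genes, which are not independent replicates, the log2 fold changes of both contrasts had a Pearson r of 0.573. It was 0.504 in the simulations, which held no territory difference either. With split controls r was 0.166, against -0.00472 in the simulations.

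**Figure D3:**
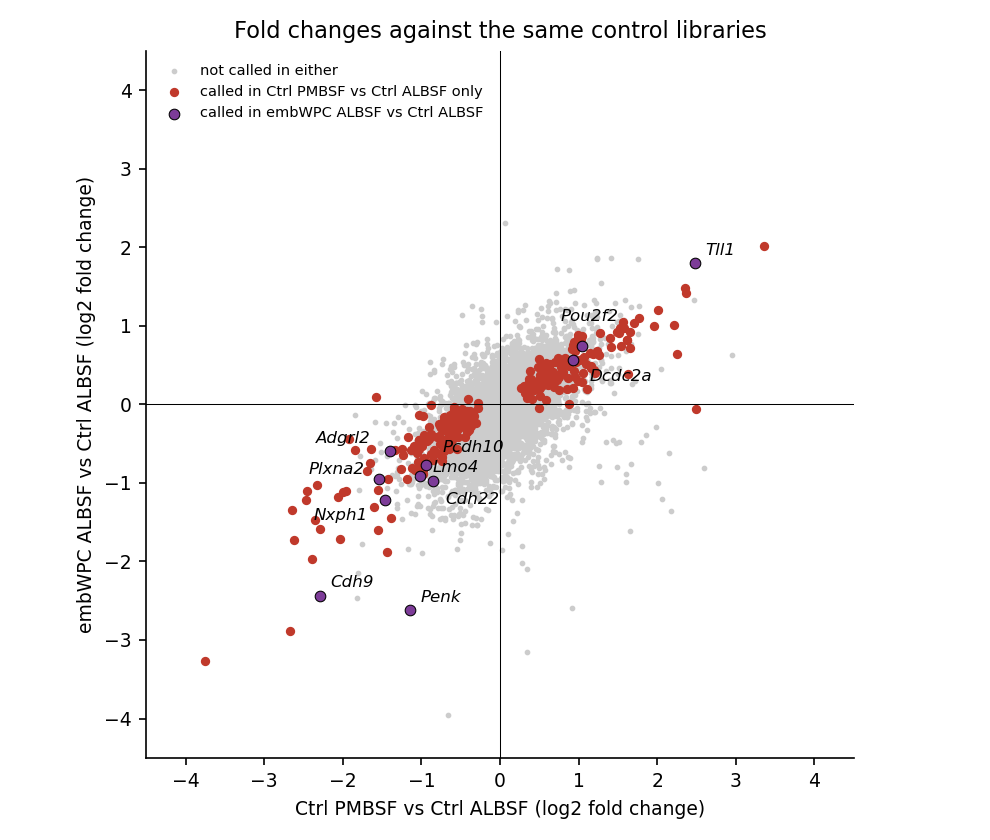
Log2 fold change of embWPC ALBSF over Ctrl ALBSF (vertical axis) against that of Ctrl PMBSF over Ctrl ALBSF (horizontal axis) for the 17501 genes tested, as 1 point each, red when called between the control territories only, purple when called in embWPC ALBSF and grey otherwise, with 1 gene outside the range of ±4.5. Of the 284 genes called between the territories, 279 had the same sign in both contrasts, which share the Ctrl ALBSF libraries.

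Comparing embWPC ALBSF with Ctrl PMBSF asks how far the treated upper lip territory still differed from the whisker pad territory. The edgeR fit called 1 gene, Adgrl2, which was 1.74-fold higher in embWPC ALBSF, at 113 ± 7.1 CPM (SD, n = 4) against 65.2 ± 1.7 CPM (log2 change 0.80 ± 0.07 (SE), adjusted p = 0.000107). It was therefore called in all 3 comparisons, with all libraries of embWPC ALBSF between those of the control territories. An unadjusted p under 0.05 was found for 1657 genes. Of 42 synaptic organisers, 1 rose, 3 rose and 3 fell adjusted over the list alone, and the list was higher at an adjusted p of 0.0103, or adjusted p = 0.490 with an estimated correlation. It was not called without Ctrl PMBSF 2 (adjusted p = 0.104). Of 30 thalamic relay neuron genes, Rorb had a log2 difference of 0.75 (adjusted p = 0.154) and Cdh6 of 0.49 (adjusted p = 0.240). For that list edgeR called 0 over all genes, 11 had an unadjusted p under 0.05, 6 rose and 1 fell adjusted over the list alone, and DESeq2 and voom called 2 and 0. The relay set was not called, at an adjusted p of 0.0669.

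All 17 meningeal markers had lower values in embWPC ALBSF than in Ctrl PMBSF, with a median of -1.68. Col3a1 had a log2 difference of -2.43 (adjusted p = 0.240) and Dcn, a proteoglycan of connective tissue, of -3.01 (adjusted p = 0.240). Over all genes edgeR called 0 of the 17, 11 had an unadjusted p under 0.05, 10 fell adjusted over the list alone, and DESeq2 and voom called 7 and 0. The list was lower at an adjusted p of 1.39e-16, or adjusted p = 0.159 with an estimated correlation. The count of 1 gene became 74 with DESeq2, 72 without a count filter, 7 with 1 surrogate variable, 3 with the replicate number as a block, 23 with the meningeal level as covariate and 2 without both control libraries numbered 1. It was 2 without Ctrl ALBSF 2 and 3 without Ctrl PMBSF 1, and Adgrl2 was called in each of these fits.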

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

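The tests of a constant share of PMBSF tissue and of the same pups behind same-numbered libraries were chosen only after the result was seen. Among 384 groups of 4 libraries, 22 held a library far from the other 3, where chance gives 19.2, or 1 in 20. In Ctrl PMBSF 1, Sp9 was at 21.3 CPM against 0.628 to 3.50 in the others, Cdh10 at 13.3 against 8.98 to 9.36, Etv1 at 12.8 against 14.9 to 15.3, Qrfpr at 1.49 against 1.90 to 1.95 and Ano3 at 0.297 against 0.644 to 0.691. In Ctrl PMBSF 3, Cntn3 was at 2.80 CPM against 1.16 to 1.32 and Tenm3 at 43.0 against 36.9 to 38.0. In Ctrl PMBSF 2, Ttr, the main transcript of choroid plexus, was at 22.0 CPM against 2.49 to 3.42. In Ctrl ALBSF 2, Ttr was at 98.7 CPM against 2.48 to 3.74, Ptgds, a meningeal marker, at 102 against 5.46 to 10.2, Col4a2 at 69.2 against 55.3 to 56.8 and Vim at 113 against 125 to 126. In Ctrl ALBSF 1, Hdc was at 6.95 CPM against 2.91 to 3.57. In Ctrl ALBSF 4, Cspg4 was at 9.62 CPM against 14.2 to 14.7 and Spp1 at 3.47 against 9.30 to 10.3. In embWPC ALBSF 1, Pcdh10 was at 21.8 CPM against 24.6 to 24.8 and Epha3 at 39.1 against 45.6 to 46.4. In embWPC ALBSF 2, Cdh6 was at 148 CPM against 175 to 179 and Vwc2l at 4.43 against 1.39 to 1.73. In embWPC ALBSF 3, Adgrl2 was at 103 CPM against 117 to 118, Ptgds at 1.79 against 3.93 to 4.36 and Islr at 0.827 against 0.629 to 0.646.

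Regrouping the libraries at random tested whether chance could give counts as large as those called. Between Ctrl PMBSF and Ctrl ALBSF the real split gave 284 genes and the highest of the other splits gave 2. So 1 of 35 splits gave as many, a share of 0.0286 and the smallest possible. This argues against chance without excluding it, and the 35 splits ignore the pairing of the control libraries. Among the 8 splits that part all 4 same-numbered pairs, the highest of the others gave 0. A share under 1 of 8 cannot be reached there, so those splits alone cannot exclude chance. Between embWPC ALBSF and Ctrl ALBSF the real split gave 11 and the highest other 0, so 1 of 35 splits gave as many. That is again the smallest share possible, which argues against chance without excluding it. Between embWPC ALBSF and Ctrl PMBSF the real split gave 1 and the highest other 1, so 2 of 35 splits gave as many and chance cannot be excluded for this count. The count does not test the gene itself, Adgrl2, which had an adjusted p of 0.000107 over 17501 genes and was called in all 25 alternatives, at adjusted p values of at most 0.0280.

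Territory genes differed in embWPC ALBSF in the direction in which Ctrl PMBSF differs from Ctrl ALBSF. Shared control libraries as the whole cause were argued against by the split-control shift, with an exact permutation p of 0.0143 over 70 assignments. Same-numbered control libraries deviate together. With Ctrl PMBSF libraries of other numbers than the held-out Ctrl ALBSF libraries the shift was 0.498, with a permutation p of 0.0143 that is not exact. The sex of the pools was argued against by the median signed difference, which was 0.419 with the Ddx3y level as covariate and 0.417 without. For 1 constant share of PMBSF tissue in every gene, the mean squared departure from a single fraction was 2.11, above the 95th percentile of 1.77 of random lists. The territory genes were called with these same libraries, which favours genes of small spread, and the random lists held only uncalled genes. That test therefore cannot decide on a constant share. The fitted fraction was 0.577 from all, 0.436 from higher and 0.698 from lower genes. By embWPC ALBSF library it ran from 0.350 to 0.563 from higher and from 0.635 to 0.762 from lower genes. A simulated constant share of 0.5 gave 0.518 from higher and 0.489 from lower genes. That check left out the calling of genes with the same controls, so this gap does not decide on a constant share either. No single gene departed from the fraction of 0.577 after adjustment in the departure test, and 37 did at an unadjusted p under 0.05. PMBSF tissue in the dissection, alone or together with other changes, litter or batch, and an effect of the treatment itself could each still contribute and stay open.

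As a set, meningeal fibroblast genes were higher in Ctrl PMBSF than in Ctrl ALBSF by camera, at an adjusted p of 1.57e-05, or adjusted p = 0.252 with an estimated correlation. They were lower in embWPC ALBSF at an adjusted p of 0.00256, or adjusted p = 0.348 with an estimated correlation. Of the 17 tested, edgeR called 0 in either comparison, 8 and 2 had an unadjusted p under 0.05, DESeq2 called 1 in each and voom 1 and 0. Within groups the list members rose and fell together from library to library, with a mean pairwise correlation of 0.276 against 0.0813 at the 95th percentile of random lists. Differing amounts of meningeal tissue in the dissections could therefore contribute, while 1 of the 18 listed genes stands on another list and all 17 tested were also counted in Ctrl ALBSF. The most abundant members included Ptgds, at 102 CPM in Ctrl ALBSF 2. An effect of territory or treatment on the meninges was not tested.

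Same-numbered libraries of Ctrl ALBSF and Ctrl PMBSF deviated together from their group means. The same pups in both libraries of number 2 were argued against by Ddx3y, a gene of the Y chromosome. It differed there by 34.6 CPM against an SD of 13.1 over the control libraries. In numbers 1, 3 and 4 it differed by 5.15, 2.00 and 1.95 CPM, under that SD, so shared pups stay open for these numbers. Autosomal genes that set both libraries of a number apart from the rest counted 8 under the real numbers and at most 6 under the other 23 pairings, which is in line with a shared genetic background of same-numbered pools. These genes included Ttr and pseudogenes, so shared dissection or library days remain open.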

How the results depend on the processing

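The Ddx3y and meningeal covariates, the block among 8 control libraries, leaving out both control libraries numbered 1, Ctrl PMBSF libraries of other numbers, and leaving out Ctrl ALBSF libraries for the shift and the correlation were tests chosen only after the data were seen. Where a cause is not given, the cause was not tested. Genes called between Ctrl PMBSF and Ctrl ALBSF, 284, numbered 527 with DESeq2, 443 with voom, 182 with the meningeal covariate and 857 with the replicate number as a block in the 8 control libraries, and 127 to 282 with 1 library left out. Counts from 194 to 398 were given by the other scalings and filters, the 8 libraries alone, the block over 12 libraries (308), 1 surrogate variable, contaminant genes left out, the fold minimum, the Ddx3y covariate and both controls numbered 1 left out. Genes called in embWPC ALBSF against Ctrl ALBSF, 11, numbered 181 with DESeq2 (44.2% higher, against 27.3%), 121 without a filter, 5 with the stricter filter, 23 with the block, 75 with voom, 34 with 1 surrogate variable, 50 without both controls numbered 1, 35 with the meningeal covariate and 1 to 37 with 1 library left out. Against Ctrl PMBSF, 1 became 74 with DESeq2, 72 without a filter, 3 with the block, 7 with 1 surrogate variable, 2 without both controls numbered 1, 23 with the meningeal covariate and 1 to 3 with 1 library left out.

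The shift of 0.508 stayed between 0.503 and 0.507 with other size factors, the stricter filter and contaminant genes left out, and ran from 0.309 to 0.659 with 1 library left out. Both ends of that range came from leaving out a Ctrl ALBSF library, where only 1 control library picked the genes. Unsplit, the shift without Ctrl ALBSF 2, 3 or 4 was 0.539, 0.570 and 0.543. With Ctrl PMBSF libraries of other numbers than the held-out Ctrl ALBSF libraries it was 0.498 (permutation p = 0.0143, not exact). It was 0.442 unsplit, 0.207 with the block unsplit, 0.518 (exact permutation p = 0.0571) unsplit without Ctrl ALBSF 1 and 0.473 (exact permutation p = 0.0571) unsplit without both controls numbered 1. Numbers did not pair embWPC ALBSF with control libraries, with same-number correlations from -0.142 to 0.0479, so the block there removes no known pairing. The correlation across genes, 0.573, was 0.166 with split controls, which drop the noise of libraries used on both sides, 0.633 without both controls numbered 1 and 0.515 to 0.638 with 1 library left out. Lists called by camera numbered 17, 22 and 13 in the 3 comparisons in the order above, and 0, 0 and 0 with an estimated correlation. Fry called 9, 0 and 0, and 23, 18 and 9 lists changed in either direction. With 1 library left out camera called 15 to 20, 9 to 24 and 9 to 18, with 13 in embWPC ALBSF against Ctrl ALBSF without Ctrl ALBSF 1 and 9 without embWPC ALBSF 1.

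The fold minimum of 1.5 is not among the alternatives counted here for named genes. Of 63 called genes named between the control territories, 35 kept their call in every alternative, 28 lost it in some, and none changed direction. Krt19 and Inhba lost theirs with the meningeal covariate, at an adjusted p of 0.0689 each, with log2 changes of -3.58 against -3.76 and -2.23 against -2.64. Of the 11 in embWPC ALBSF against Ctrl ALBSF, Adgrl2 kept its call in all alternatives and 10 lost it in some. The fold minimum left 10 of the 11, without Dcdc2a at a log2 change of 0.564. Besides libraries left out, calls were lost in the 8 libraries alone (Pou2f2, Dcdc2a, Nxph1 and Pcdh10, adjusted p of 0.0571 to 0.0750), with the block (Pou2f2 and Lmo4, 0.0527 and 0.0591), with the Ddx3y covariate (Nxph1 and Pcdh10, 0.0513 each) and with the meningeal covariate (Pou2f2, Dcdc2a, Plxna2 and Lmo4, 0.0626 to 0.0918, with log2 changes of 0.751, 0.536, -0.777 and -0.884). Directions turned for 2 lists and for check genes. The oxidative phosphorylation list in embWPC ALBSF against Ctrl ALBSF was lower at an adjusted p of 0.00316 (adjusted p = 0.679 with an estimated correlation), ran from an adjusted p of 4.86e-08 to 0.639 with 1 library left out, and turned upward without embWPC ALBSF 4 (0.639). The ribosomal list against Ctrl PMBSF was lower at 0.0364 (adjusted p = 0.803 with an estimated correlation), ran from 1.70e-06 to 0.257, and was called as higher without embWPC ALBSF 4 (0.0395). It was not called without Ctrl PMBSF 2 (0.196), Ctrl PMBSF 4 (0.257) or embWPC ALBSF 2 (0.232). Between the control territories, log2 changes were -0.69 for Ddx3y and -0.66 for Eif2s3y with the meningeal covariate. With 1 library left out they ran from -0.00717 to 0.0686 for Slc17a6, from -0.12 to 0.80 for Gad2 and from -3.23 to 1.33 for Ttr. In embWPC ALBSF against Ctrl ALBSF, Xist was at 0.15 with the block, 2.33 with voom and -1.03 to 0.58 with 1 library left out. Gad2 was at 0.0910 without both controls numbered 1 and -1.19 to 0.0888 with 1 left out, and Ttr ran from -2.87 to 0.68. Against Ctrl PMBSF, the block gave 0.0751 for Ddx3y, 0.0766 for Eif2s3y and 0.36 for Ttr, and the meningeal covariate gave -1.64 for Xist, 1.79 for Ddx3y, 1.76 for Eif2s3y, 3.84 for Ttr and 0.0136 for Hbb-bs. With 1 library left out the ranges were -0.38 to 0.19 for Ddx3y, -0.40 to 0.17 for Eif2s3y, -0.0227 to 0.0719 for Slc17a6 and -1.05 to 0.77 for Ttr. With the meningeal covariate the SE against Ctrl PMBSF was 2.10 for Xist, 1.51 for Ddx3y and 1.72 for Ttr. Each embWPC ALBSF library lay below every control library in meningeal level, so that covariate is partly confounded with group.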

Other observations

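Further lists of cell type and cell state were called. Of 53 cytosolic ribosomal protein genes, 3 had higher values in embWPC ALBSF than in Ctrl ALBSF, and the list was lower at an adjusted p of 1.79e-05 by camera, or adjusted p = 0.582 with an estimated correlation. Without embWPC ALBSF 4 the ribosomal list was not called, at an adjusted p of 0.593. Of 18 microglia and macrophage markers, 2 had higher values and the list was lower at an adjusted p of 0.000413, or adjusted p = 0.401 with an estimated correlation. Of 24 hypoxia and glycolysis genes, 17 had higher values and the list was higher at an adjusted p of 0.0292, or adjusted p = 0.348 with an estimated correlation. The hypoxia list was not called without Ctrl ALBSF 2 (adjusted p = 0.10), Ctrl ALBSF 4 (adjusted p = 0.0833) or embWPC ALBSF 1 (adjusted p = 0.161). Of 32 activity-regulated immediate early genes, 22 had higher values in embWPC ALBSF than in Ctrl PMBSF, and the list was higher at an adjusted p of 0.00806, or adjusted p = 0.182 with an estimated correlation. Between Ctrl PMBSF and Ctrl ALBSF, 7 of the 32 had higher values and the list was lower at an adjusted p of 0.0241, or adjusted p = 0.192 with an estimated correlation. It was not called there without Ctrl ALBSF 1 (adjusted p = 0.104) or Ctrl PMBSF 4 (adjusted p = 0.0603). Between embWPC ALBSF and Ctrl ALBSF, 18 had higher values and the list was not called, at an adjusted p of 0.855, with a median of 0.01 against a mean of -0.00 and an upward test.

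Over all 36 lists, 17 were called between the control territories (1 higher, 16 lower), 22 in embWPC ALBSF against Ctrl ALBSF (2 higher, 20 lower) and 13 against Ctrl PMBSF (7 higher, 6 lower), and 0 in each with an estimated correlation. Xist, which marks female cells, ran from 0.07 to 68.7 CPM in Ctrl ALBSF, from 0.06 to 21.6 in Ctrl PMBSF and from 7.41 to 36.6 in embWPC ALBSF. Ddx3y, which marks male cells, ran from 0 to 31.9, from 6.56 to 34.6 and from 9.64 to 33.7 CPM. Xist had a log2 difference of -1.53 between Ctrl PMBSF and Ctrl ALBSF (adjusted p = 0.678) and Ddx3y of 0.54 (adjusted p = 0.855), so the share of female and male pups varied between the pools of a group.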
